A study of Homo sapiens with 2 samples.

How the data were processed

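Gene expression was measured in 2 samples labelled HL60, a human promyelocytic leukaemia cell line, 1 left untreated and 1 exposed to eltrombopag, a small-molecule agonist of the thrombopoietin receptor that also binds iron. Per the labels' protocols, the cells grew in RPMI with 10% serum, the drug was given at 3 µg/ml for 36 h, RNA was extracted with Trizol, and biotinylated cRNA was prepared from about 5 µg of total RNA by the Affymetrix protocol. No culture time was recorded here for the untreated sample, and its label names no vehicle. The table deposited by the authors holds 1 signal intensity per probe set and sample, on a linear scale; MAS5 is named in the submitters' processing notes, and its version, scaling target and detection calls are not given in the sources used here. MAS5 corrects background and combines the perfect-match and mismatch probes of a probe set within each array, so low signals carry large relative error. Neither the table nor the labels give probe-level data, and the number of arrays, 1 per group, limits the precision.

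The table holds 54613 probe sets. The median signal was 32.8 in the untreated and 31.5 in the eltrombopag sample, and the mean without the highest and lowest 2% was 176.6 and 164.9, so the values held here do not share 1 average. Exactly 1 was recorded for 935 probe sets in the untreated and 901 in the eltrombopag sample, and the lowest values were 0.77 and 0.58. Control probe sets are not among the values used here, so the planned 3′ to 5′ ratios of actin and GAPDH, a check of RNA quality, were not computed. Gene names came from the platform annotation: 41091 probe sets named 1 gene, 1801 named several and were left unnamed, and 11721 were not listed. Of the probe sets with 1 gene, 41037 had an identifier in the RefSeq gene table of assembly GRCh38.p14, which was used to update symbols and changed 0 of them; 5 older symbols in the gene lists were replaced. Genes with no probe set named for them alone, some members of the gene lists included, were not analysed here. No genome build is given for the array, so no coordinates are printed.

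The following rules were fixed before the data were examined. Values were taken as deposited. A floor was set at the 60th percentile of both samples pooled, a signal of 56.9. Signals below it were raised to it before log2 was taken. A fold change with 1 side at the floor is a lower bound. For a gene with several probe sets, the one with the highest mean log2 signal was used. Of 19775 genes, 10314 lay above the floor in at least 1 sample and are called measured, and 9597 lay above it in both. With 1 sample per group, no test of the treatment can be made and no p-value, SD or SE between samples is given; genes were counted where the log2 ratio of eltrombopag over untreated was at least 1 in size, a 2-fold change. The 34 gene lists were fixed with their members. For each list with at least 5 measured members, the median log2 ratio was placed among the medians of 10000 random lists of equal size, matched on mean signal in 20 bins. A list is said to stand apart below percentile 2.5 or above 97.5. The percentile describes these 2 arrays and is no test of the treatment. The lists overlap in part. About 5% of random lists lie outside these limits by construction. Random lists hold genes drawn independently, so this share need not hold for lists of genes that vary together.

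Named genes followed a fixed rule. It took the 10 genes with the largest log2 ratio in each direction among those above the floor in both samples. It also took the 5 brightest in each direction that lay at the floor in the other sample. Both groups left out genes with a probe set above the floor in both samples that moved the other way. Up to 4 members per list with the largest change and a fixed panel were added. Any gene outside the rule is marked as chosen after its values were seen. The only measure of error within these arrays is the disagreement between probe sets of 1 gene. It was computed for the 2 brightest probe sets of 4374 genes and is not an error between replicates.

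The alternatives were median centring, quantile normalization and lowess (span 0.3) of the 2 arrays, floors at the 50th and 75th percentiles or none (values below 1 raised to 1), the mean over probe sets, the omission of probe sets with the suffixes _x_at and _s_at, thresholds of 1.5-fold and 3-fold, agreement of at least 2 probe sets, the mean in place of a list's median, and members above the floor in both samples alone. The gene count was tested on simulated data with noise of the size seen between probe sets (SD 0.26 on the log2 scale). Over 19775 simulated genes for eltrombopag against untreated, changes of 1.5 and 2.5 were called in 50 of 50 genes each, changes of -1.5 in 46 of 50 and of -2.5 in 45 of 50, and 1 of 9946 unchanged genes was called. That simulation leaves out variation between cultures. A simulated list of 30 genes with a shift of 0.5 reached percentile 100, and an unshifted one 34.1. Computations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9.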

Results

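Transcript levels were measured on expression arrays in 2 samples, 1 untreated culture labelled HL60 and 1 exposed to eltrombopag at 3 µg/ml for 36 h, to find genes whose expression differs after treatment. Each group holds 1 sample, so every difference below is a difference between 2 arrays, without a replicate check. Whether the untreated sample was matched in culture time or vehicle is not known here. An effect of the drug cannot be told apart from a difference in either. Values are MAS5 signals, a linear measure of brightness per probe set, and ratios are eltrombopag over untreated. Of the probe sets, 40.7% lay at or above the floor in the untreated and 39.3% in the eltrombopag sample. Across 20698 probe sets above the floor in both samples, log2 signals correlated with Pearson's r = 0.965 and Spearman's rho = 0.957, a figure across probe sets, which are not independent replicates.

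The lists of cholesterol synthesis genes and of endoplasmic reticulum chaperones had higher medians than random lists, though not all of their members were higher, and the lists of DNA replication genes and metallothioneins had lower ones. The transferrin receptor and the inflammatory mediators CXCL8 and CCL5 were higher in the eltrombopag sample, while TNF, named after its values were seen, was lower. Several genes typical of plasma cells were also lower. Of 18 plasma cell genes chosen after values had been seen, 16 lay above the floor in both samples. Among 10314 measured genes, 67 were at least 2-fold higher and 234 at least 2-fold lower. For 7 of the higher and 22 of the lower genes, the probe set used lay at the floor in the other sample, so its fold is a lower bound. The median log2 ratio of the 9597 genes above the floor in both samples was -0.12, with quartiles of -0.37 and 0.11. Higher genes made up 22.3% of the 2-fold changes on the deposited scale, 38.6% after median centring, 43.2% after lowess and 44.8% after quantile normalization, so the balance between the directions depended on how the arrays were scaled. Gene lists are therefore described against random lists from the same arrays, which carry the same overall shift, while counts of list members above or below 0 include it.

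**Figure D1:**
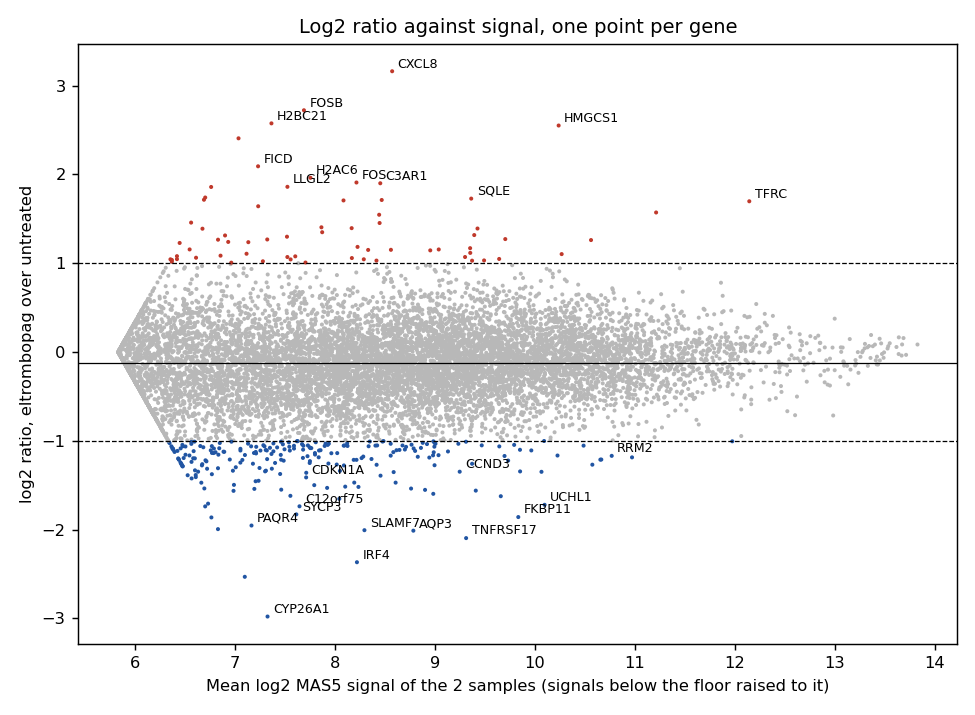
Log2 ratio of eltrombopag over untreated against the mean log2 signal, 1 point per measured gene; dashed lines mark 2-fold, the solid line the median of -0.12, red points the 67 genes at least 2-fold higher and blue points the 234 at least 2-fold lower. CXCL8, FOSB and HMGCS1 lie far above most genes of like signal, and CYP26A1 and IRF4 far below.

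The largest increase among genes above the floor in both samples was that of CXCL8, the neutrophil chemokine interleukin-8, from a signal of 127.2 to 1138, or 8.95-fold. This value rests on 1 probe set, which carries the suffix _x_at. The other CXCL8 probe set lay below the floor in both samples, at 17.15 untreated and 47.43 with eltrombopag. FOSB and FOS, subunits of the AP-1 transcription factor, were 6.60-fold and 3.75-fold higher. The histone genes H2BC21 and H2AC6 were 5.96-fold and 3.90-fold higher; their probe sets carry the suffix _s_at, and histone genes are similar enough in sequence for signal to be shared. HMGCS1 and SQLE, enzymes of cholesterol synthesis, were 5.86-fold and 3.31-fold higher, and a dimmer SQLE probe set had a log2 ratio of 0.93. FICD, which modifies the chaperone BiP, was 4.26-fold higher, C3AR1, a complement receptor, 3.73-fold, and LLGL2, a cell polarity gene, 3.63-fold. The LLGL2 probe set used carries the suffix _s_at. Another LLGL2 probe set, below the floor in both samples, went down from 47.48 to 25.98. Of genes whose brightest probe set lay at the floor in the untreated sample, SEC24D, a COPII coat component that takes part in export from the endoplasmic reticulum, was at least 5.30-fold higher in it, but had a log2 ratio of 1.34 in the probe set above the floor in both samples. PPP1R15A, a regulatory subunit of the phosphatase acting on eIF2α, was at least 3.63-fold higher in its brightest probe set and below 2-fold, with a log2 ratio of 0.90, in the one above the floor in both samples. TINCR was higher by at least 3.34-fold, SELENOP, a secreted selenoprotein, by at least 3.28-fold and NOG, a secreted BMP antagonist, by at least 2.75-fold.

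In the other direction, CYP26A1, the retinoic acid hydroxylase, was 7.88-fold lower, from 450.0 to 57.1, just above the floor. IRF4, a transcription factor of lymphocytes and plasma cells, was 5.16-fold lower, TNFRSF17, the receptor BCMA, 4.28-fold, and SLAMF7, a surface receptor abundant on plasma cells, 4.02-fold. AQP3, an aquaporin, was 4.03-fold lower, PAQR4 3.88-fold, FKBP11 3.63-fold, SYCP3, a meiotic chromosome protein, 3.55-fold, C12orf75 3.34-fold and UCHL1, a deubiquitinase, 3.30-fold. ITGA8, an integrin subunit, was at least 5.78-fold lower, GJB2, a connexin, at least 3.99-fold, UNC13C at least 3.64-fold, GDAP1 at least 3.34-fold and ILDR2 at least 2.62-fold. The other probe sets above the floor in both samples were lower too, with log2 ratios of -2.17 and -0.69 for FKBP11, but with only -0.44 for AQP3 and -0.39 for SLAMF7, and the remaining 7 of these 10 top genes had 1 such probe set each.

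Genes of iron handling and of the response to low oxygen were compared because eltrombopag binds iron. TFRC, the transferrin receptor that carries iron into cells, was 3.24-fold higher, from 2517 to 8162, and its second probe set above the floor in both samples had a log2 ratio of 1.08. Another TFRC probe set, at the floor in the eltrombopag sample, gave -0.76, and the mean over its measured probe sets was 0.67, below 2-fold. TFRC was the only one of 20 measured iron uptake, export and storage genes to differ by 2-fold; 6 had a ratio above 0 and 14 below, and the list's median of -0.06 lay at percentile 66.6 of random lists. SLC39A8, a metal transporter, had a log2 ratio of -0.63, NCOA4, the ferritin autophagy receptor, -0.42, and FTL, the ferritin light chain, -0.23 in its brightest probe set and -0.61 in another. SLC11A2, the iron transporter DMT1, gave 0.54 in its brightest probe set but -0.18 and -0.02 in the others above the floor in both samples. HMOX1, heme oxygenase, lay below the floor in both samples.

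Targets of the hypoxia-inducible factor HIF did not stand apart. Of 29 measured HIF targets other than glycolysis genes, 0 were at least 2-fold higher and 1, BHLHE41, was 2.19-fold lower, and the median of -0.11 lay at percentile 48.7. NDRG1, BNIP3 and VEGFA had log2 ratios of 0.21, 0.13 and 0.16. HILPDA and AK4 had ratios of -0.97 and -0.95. Of 21 glycolysis genes, none differed by 2-fold, 19 had a ratio below 0, LDHA had -0.96, PDK1 -0.78 in its brightest probe set and -1.88 and 0.55 in others, and SLC2A3, a glucose transporter, 0.71, and the list lay at percentile 11.6. The iron-sulfur cluster assembly list lay at percentile 4.22, with FDX1 at -0.85, and the list of iron-dependent histone and DNA demethylases at percentile 96.4, with KDM6B at 0.67; none of the 19 and 26 measured members differed by 2-fold.

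The cholesterol synthesis list was higher than every random list. Of 18 measured members, 7 were at least 2-fold higher, 1 was at least 2-fold lower and 10 lay between, and the median log2 ratio was 0.70 against -0.32 to 0.07 for the central 95% of random lists. After HMGCS1 and SQLE came DHCR7, the last enzyme of the pathway, at 3.28-fold (log2 ratio 0.78 in another probe set), MSMO1, a sterol methyl oxidase, at 2.97-fold and SREBF2, the transcription factor that drives the pathway, at 2.74-fold. PMVK, phosphomevalonate kinase, was 2.13-fold lower; SREBF2 and PMVK are named after their values were seen. The fatty acid synthesis list stood apart on the higher side at percentile 99.6, with a median of 0.23 over 11 genes. Its 1 gene past 2-fold was ACSS2, an acetyl-CoA synthetase, at 3.26-fold, while the probe sets of ACACA and of SCD disagreed. ACACA had log2 ratios of 0.47 and -0.39, and SCD had 0.42 and 0.14 in its brighter probe sets, -0.90 and -1.65 in dimmer ones and -0.50 as their mean, so neither has a settled direction. This list fell to percentile 94.9 with the mean over probe sets and 95.5 without probe sets of the suffixes _x_at and _s_at.

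Stress genes of the endoplasmic reticulum were higher as a list. Of 19 measured endoplasmic reticulum chaperones, 2 were at least 2-fold higher, MANF at 2.40-fold and HYOU1 at 2.10-fold, 0 were at least 2-fold lower, 5 had a ratio below 0, and the median of 0.34 exceeded every random list. HSP90B1 and CRELD2 had log2 ratios of 0.94 and 0.93 and passed 2-fold after median centring, quantile normalization and lowess, which each gave 4 members at least 2-fold higher. The ATF4 and amino acid stress response list, with a median of 0.13 over 32 genes, also exceeded every random list, although 18 members had a ratio above 0 and 14 below. PPP1R15A was its 1 member past 2-fold, in its brightest probe set alone; ASNS, asparagine synthetase, had a ratio of 0.68, SLC7A5, an amino acid transporter, -0.84 and ALDH18A1, of proline synthesis, -0.64. The cytosolic heat shock list did not stand apart, at percentile 17.1 over 12 genes, with HSPE1 at -0.99, DNAJA1 at -0.55, BAG3 at -0.42 and DNAJB1 at -0.41.

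DNA replication and nucleotide supply genes were lower as a group. Of 46 measured members, 9 were at least 2-fold lower and 0 at least 2-fold higher, 41 had a ratio below 0, and the median of -0.60 lay below every random list, whose central 95% spanned -0.23 to 0.01. The count of 2-fold lower members was 8 after median centring, 7 after lowess and 6 after quantile normalization. UHRF1, which maintains DNA methylation at replication, was 2.54-fold lower, GINS2, a subunit of the replicative helicase, at least 2.43-fold, CCNE2, cyclin E2, 2.42-fold, PCNA, the polymerase clamp, 2.32-fold and RRM2, the iron-containing subunit of ribonucleotide reductase, 2.25-fold. Mitosis genes were lower by less: none of 40 differed by 2-fold and the median was -0.25. The list lay at percentile 0.69, but at 3.63, within the limits, without probe sets of the suffixes _x_at and _s_at. KIF11, CCNB1 and BIRC5 had log2 ratios of -0.74, -0.66 and -0.65.

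Among 22 measured G1 regulators, CDKN1A, the inhibitor p21, was 2.66-fold lower, CCND3, cyclin D3, 2.55-fold lower and E2F2 2.07-fold lower. The list lay at percentile 3.44. It stayed within the limits under 5 of 10 alternatives and stood apart on the lower side under the others. E2F2 was below 2-fold under each of the 3 other scalings, with log2 ratios of -0.95, -0.93 and -0.93. CCND1, CCND2 and MYC had log2 ratios of 0.02, -0.26 and -0.12. The p53 target list stood apart on the lower side at percentile 1.48, but lay at 3.23, within the limits, with the floor at the 75th percentile. Of its 21 genes, 19 were below 0 and CDKN1A was the 1 member past 2-fold. PPM1D and TP53INP1 had ratios of -0.76 and -0.70. The BCL2 family did not stand apart, at percentile 13.6 over 15 genes, with BCL2L13 at -0.89 and BIK at -0.76.

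Metallothioneins, small proteins that bind zinc and copper, were lower in 6 of 6 measured genes. MT2A was 2.33-fold and MT1G 2.29-fold lower, MT1F and MT1E had log2 ratios of -0.82 and -0.79, and the list's median of -0.80 lay at percentile 0.02. The probe sets used for the genes named here carry the suffix _x_at, and the family shares sequence, so these are not 6 independent measurements. Heme synthesis genes were lower as a list, with 8 of 9 below 0, a median of -0.54 and percentile 0.40; UROD, UROS and FECH had ratios of -0.85, -0.78 and -0.66, with 0.19 in another FECH probe set, and none reached 2-fold. Oxidative phosphorylation genes had a median of -0.25 with 34 of 37 below 0 and lay at percentile 0.15; ATP5MC1, ATP5MC3 and UQCRQ had ratios of -0.96, -0.85 and -0.83. NRF2 targets lay at percentile 1.83 with a median of -0.30, but only by a margin that ended under 4 alternatives; NQO1, TXN and PRDX1 had ratios of -0.88, -0.81 and -0.79, with -0.25 in another NQO1 probe set.

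The remaining pathway lists were mixed. The NF-kB and inflammatory cytokine list stood apart on the higher side at percentile 99.99, with a median of 0.36 over 13 genes. Of these, 4 were at least 2-fold higher: CXCL8, CCL5, a T-cell chemokine, at 2.55-fold, and NFKBIA and TNFAIP3, feedback inhibitors of NF-kB, at 2.49-fold and 2.41-fold, while TNF, named after its values were seen, was at least 2-fold lower with a log2 ratio of -1.05. Of 14 STAT5 and JAK-STAT feedback targets, the pathway the thrombopoietin receptor uses, FOS was the 1 gene past 2-fold, PIM2 had a ratio of -0.81, and the list lay at percentile 36.0. The interferon response list lay at percentile 49.0, with GBP2 at least 2.34-fold higher and HERC5 at -0.99. The lysosome and autophagy list lay at percentile 3.39, with CTSA at -0.82 and NPC2 at -0.75, ribosome biogenesis at 93.7, with LYAR at 0.73 and NOP10 at -0.69, and cytosolic ribosomal proteins at 14.7, with RPL30 at -0.65. Of 4 measured aryl hydrocarbon receptor targets, too few to place the list, CYP1B1 was 2.09-fold lower and AHRR had a ratio of -0.35; CYP1A1 lay below the floor in both samples.

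**Figure D2:**
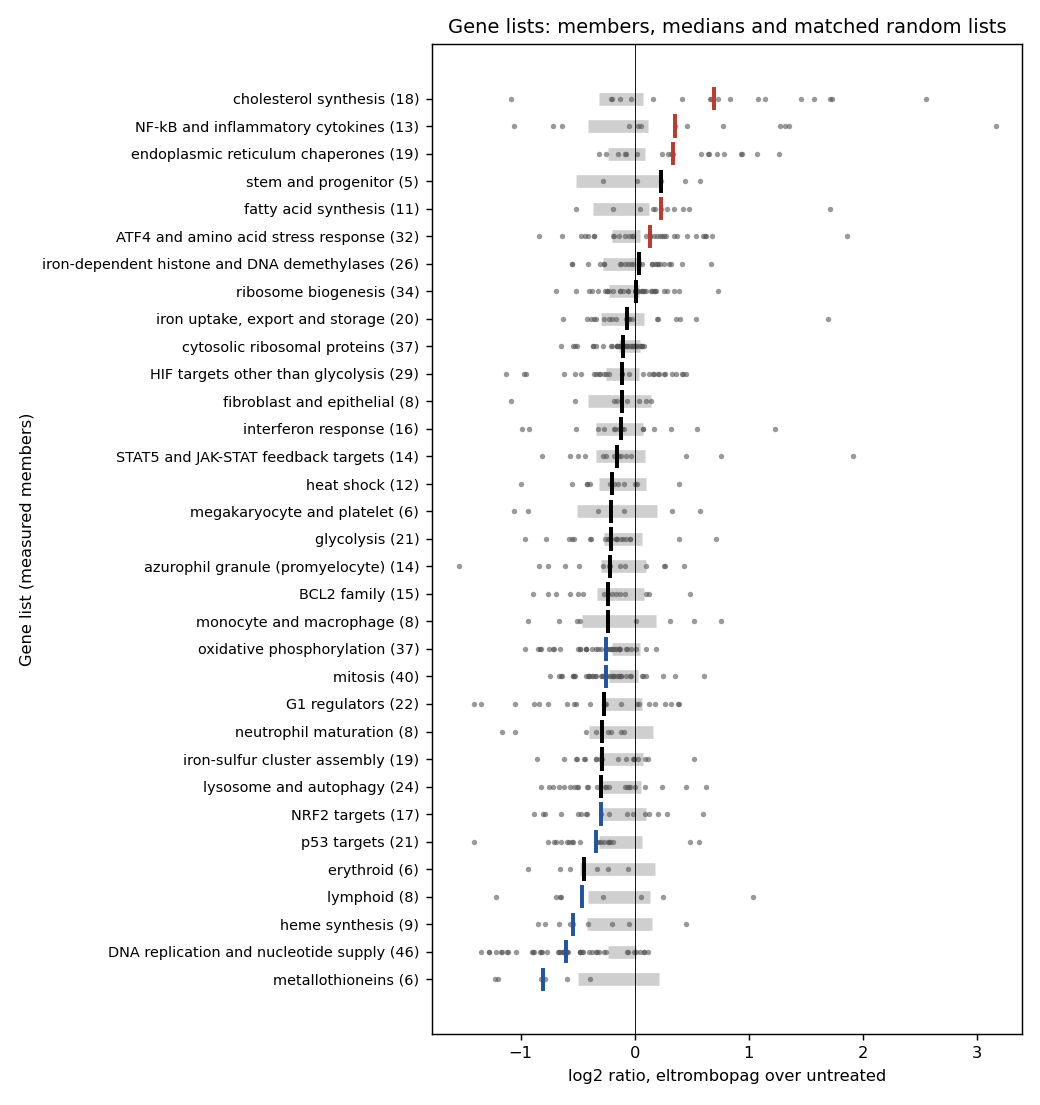
Log2 ratio of eltrombopag over untreated for the measured members of each gene list (grey points; number of members in brackets), with the list's median (bar) and the central 95% of medians of 10000 matched random lists (grey band). Bars are red for lists that stand apart on the higher side, blue on the lower side and black otherwise; the cholesterol synthesis median of 0.70 and the metallothionein median of -0.80 lie farthest out.

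Blood lineage markers showed no shift towards a mature lineage as lists. Of 8 measured neutrophil maturation genes, 8 had a ratio below 0; CSF3R, the G-CSF receptor, was 2.25-fold lower and CYBA, of the NADPH oxidase, 2.07-fold lower, though a dimmer CYBA probe set gave 0.015, and the list lay at percentile 11.1. The list of azurophil granule and other promyelocyte genes lay at percentile 10.6. In it, IGFBP2 was 2.91-fold lower, but below 2-fold, at -0.55, with the floor at the 75th percentile. CTSG had a ratio of -0.84 and MPO, myeloperoxidase, -0.08. The monocyte and macrophage list lay at percentile 26.4, with CD9 at -0.93 and EGR1 at 0.76; CD14 lay below the floor in both samples, and ITGAM, at 62.0 and 41.1, was above it in the untreated sample alone. The megakaryocyte and platelet list lay at percentile 36.2, with NFE2 2.09-fold lower. The erythroid list lay at percentile 3.58, with HBD at -0.93, and the stem and progenitor list at 97.4, with SPINK2 at 0.57. Between 5 and 14 members of each of these lists were measured.

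Lists of other cell types were mostly below the floor, while many plasma cell genes were above it. The lymphoid list, of which 8 of 25 genes on the array were measured, lay at percentile 1.08, with PAX5, a B-cell transcription factor, at least 2.32-fold lower and BLNK, a B-cell adaptor, 2.05-fold higher, but it moved to percentile 64.2 with the floor at the 50th percentile and to 97.1 without a floor. The fibroblast and epithelial list, with 8 of 22 genes measured, lay at percentile 49.1, with SPARC at least 2.12-fold lower. Because IRF4, TNFRSF17 and SLAMF7 were among the largest decreases, 18 plasma cell genes and 18 genes of promyelocyte and myeloid identity were examined, both sets chosen after values had been seen. Of the plasma cell genes, 16 lay above the floor in both samples. IGLC1, an immunoglobulin lambda constant gene, had signals of 10395 and 6331 in the untreated and eltrombopag sample, JCHAIN, the immunoglobulin joining chain, 7972 and 4866, and XBP1 3441 and 3268. Of the myeloid genes, 13 lay above the floor in both samples, among them MPO at 1556 and 1467, MS4A3, CEBPE and GFI1, while ELANE, neutrophil elastase, LYZ, lysozyme, and SPI1, the transcription factor PU.1, lay below it in both. Of the 16 measured plasma cell genes, 7 were at least 2-fold lower and 0 at least 2-fold higher, a count that includes the genes that prompted the list and so says nothing about plasma cell genes as a group.

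**Figure D3:**
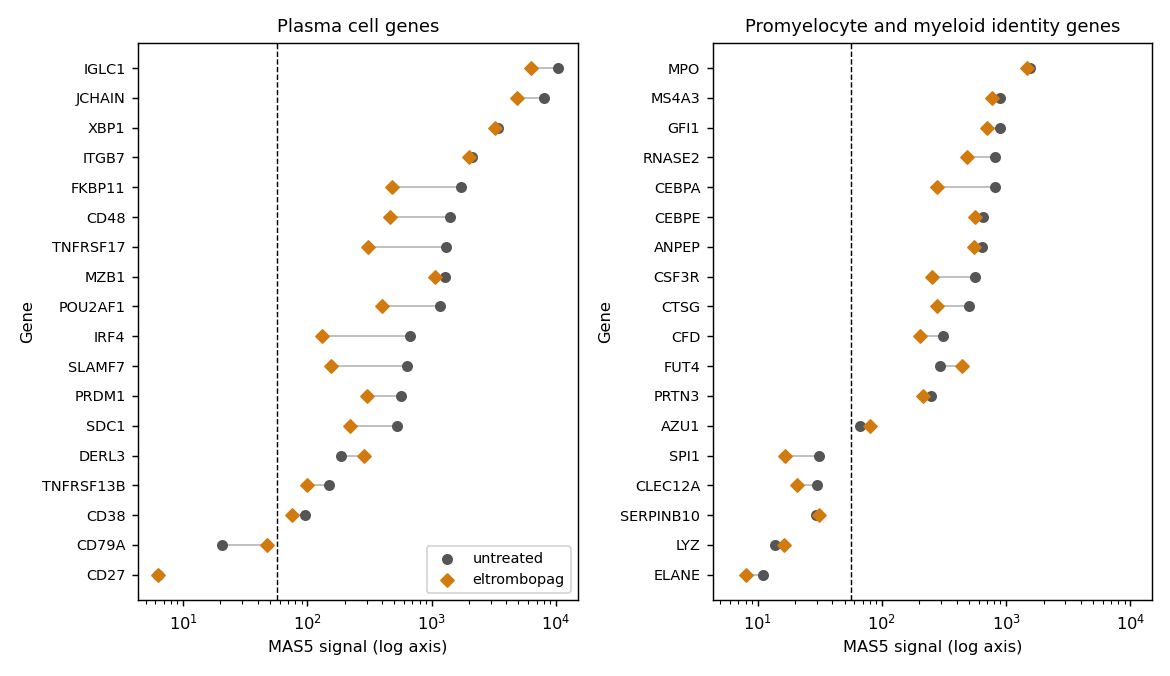
MAS5 signal (log axis) of plasma cell genes and of promyelocyte and myeloid identity genes in the untreated (circles) and eltrombopag (diamonds) sample; the dashed line is the floor of 56.9. Both gene sets hold members far above the floor in both samples, and ELANE, LYZ and SPI1 lie below it.

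The spread available within these arrays is that between probe sets of 1 gene. Over 4374 genes the log2 ratios of the 2 brightest probe sets differed with an SD of 0.37, or 0.26 per probe set. With genes split by signal into 3 equal groups, the value per probe set was 0.29 in the dimmest and 0.21 in the brightest group. Of 64 genes 2-fold changed in the brighter probe set, 61 moved the same way in the second and 30 also by 2-fold, against 72.1% with the same direction among genes changed by less. Of the genes just past 2-fold, CYBA, CYP1B1, NFE2, PMVK and TNF were below it after median centring, quantile normalization and lowess, and BHLHE41 after the latter 2. With the floor at the 75th percentile FICD, PAQR4 and IGFBP2, whose dimmer sample lay near the floor, were below 2-fold, with log2 ratios of 0.86, -0.73 and -0.55. Variation between cultures is not part of this spread, so no statement on reproducibility follows from it.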

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

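The tests of explanations in this part were chosen after the data were seen. Probe sets without a single gene name take no part in the comparison of genes, yet some changed: of 4360 above the floor in at least 1 sample, 44 were at least 2-fold higher and 67 at least 2-fold lower in the eltrombopag sample, or 1.01% and 1.54%. Among probe sets with 1 gene the shares were 0.65% and 2.30%. No explanation was tested for this difference in balance.

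Plasma cell genes were present in samples labelled as a promyelocytic line: 16 of 18 lay above the floor in both samples. Without the 4 taken for their large decrease, which had to lie above the floor, it was 12 of 14, against 48.5% of all genes, but the list was drawn up with values in view and no profile of a reference HL60 culture was at hand, so these counts do not exclude myeloid cells alone. Only 2 of 9 IGLC1 probe sets lay above the floor in both samples, both with the suffix _x_at, and JCHAIN has 1 probe set. Of the 12 genes with several probe sets, 8 had at least 2 above the floor in both samples. For these genes, this argues against cross-hybridisation of a single probe set as the whole cause. IGLC1 is among them through its 2 _x_at probe sets alone, so it is weak support. The share over all genes with several probe sets was not computed. Of 18 myeloid identity genes, 13 were also above the floor in both samples, while 5, among them ELANE, LYZ and SPI1, lay below it in both. Myeloid cells that express the plasma cell genes, a culture holding a second cell type and a line other than the label says cannot be told apart, because no genotype was measured. Each of these may apply, and values in the comparisons above belong to the cells in these samples, whatever their line.

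Several plasma cell genes were also lower in the eltrombopag sample, among them IRF4, TNFRSF17, SLAMF7 and FKBP11, which were among the 10 largest decreases. The list was drawn up after such decreases were seen and holds them, so it cannot test whether plasma cell genes fell as a group. A smaller share of plasma cells would lower all of these genes by about the same factor. Over the 14 genes whose probe sets above the floor in both samples moved 1 way, log2 ratios ran from -2.37 for IRF4 to -0.07 for XBP1. Their SD was 0.77, against 0.26 for 1 probe set. The 14 include the 4 genes taken for their large decrease, which widens this spread. DERL3, at 0.63 and -0.53 in its probe sets, and MZB1, at 0.09 and -0.28, are not among them. The spread between cultures was not measured and XBP1 is not limited to plasma cells, so a smaller share, regulation of single genes and a difference between cultures cannot be told apart. Of the 18 genes, 2 are also in the lists fixed beforehand.

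TFRC was higher without a general rise of HIF targets. A fault of the brightest probe set alone is argued against by the second TFRC probe set above the floor in both samples, with a log2 ratio of 1.08, although a dimmer one, at the floor in the eltrombopag sample, gave -0.76 and the mean over probe sets, 0.67, was below 2-fold. A general rise of HIF targets is argued against by the list's place at percentile 48.7, with 0 of 29 genes at least 2-fold higher, and the list stayed within the limits under all 10 alternatives, between percentiles 26.2 and 93.4. Iron shortage sensed through iron-responsive elements, which stabilise TFRC mRNA, is a candidate explanation that stays open: SLC11A2, with such an element in some of its transcripts, gave 0.54 in 1 probe set and lower values in others.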

How the results depend on the processing

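No paired analysis was possible because each group holds 1 sample, and for the same reason no sample could be left out. The counts of 2-fold higher and lower genes were 104 and 137 after lowess and 108 and 133 after quantile normalization; after median centring 154 were lower. Median centring, quantile normalization and lowess raised the median log2 ratio from -0.12 to -0.02, -0.01 and -0.02. Raised ratios favour higher calls, so it is no check of the 67 higher genes that all kept theirs. Of the 234 lower genes, 154 kept their call after median centring, 137 after lowess and 133 after quantile normalization. The 3 medians were nearly equal, so the median shift alone does not account for the differences between these counts. With the floor at the 75th percentile the counts were 37 and 98, without a floor 1195 and 1324, at 1.5-fold 360 and 1215, at 3-fold 18 and 19, and with at least 2 agreeing probe sets 19 and 40, since these settings test other genes or sizes. The lists for cholesterol synthesis, endoplasmic reticulum chaperones, ATF4 and amino acid stress, NF-kB, DNA replication, oxidative phosphorylation, heme synthesis and metallothioneins kept their side under every alternative that gave a value; metallothioneins had too few members for 2. Over all lists, 281 alternatives left the call as it was, 19 created one, 12 ended it with the list on the same side of the middle of random lists, and 2 ended it with the list on the other side. For the lists below, the cause was not tested. Calls that ended were NRF2 targets at percentile 4.02 and 3.75 with the floor at the 50th and 75th percentiles, 5.25 with the mean in place of the median and 6.66 without _x_at and _s_at probe sets; lymphoid at 3.15 (lowess), 17.8 (quantile normalization), 17.2 (mean) and 16.1 (without those probe sets); fatty acid synthesis at 94.9 (mean over probe sets) and 95.5 (without those probe sets); mitosis at 3.63 (without those probe sets); and p53 targets at 3.23 (75th percentile floor). The lymphoid list moved to the other side of the middle, within the limits, at 64.2 with the floor at the 50th percentile and 97.1 without a floor. Calls that appeared were G1 regulators at 2.49 (75th percentile floor), 2.23 (lowess), 1.56 (quantile normalization), 0.29 (mean) and 1.57 (without _x_at and _s_at probe sets); erythroid at 0.74 (50th percentile floor), 2.33 (lowess) and 1.81 (quantile normalization); neutrophil maturation at 1.04 (mean), 0.99 (mean over probe sets) and 0.59 (without those probe sets); ribosomal proteins at 2.41 (mean) and 0.81 (without those probe sets); lysosome and autophagy at 2.43 (75th percentile floor) and 1.79 (without those probe sets); the BCL2 family at 1.36 (no floor); and iron-dependent demethylases at 98.1 (lowess), 97.9 (quantile normalization) and 99.1 (mean over probe sets). Of the named genes past 2-fold, CYBA changed sign, to 0.015, without _x_at and _s_at probe sets. Of those below 2-fold, SCD changed sign, to -0.50, and SLC11A2, to -0.026, with the mean over probe sets, and SLC11A2, to -0.43, and TET1, from -0.55 to 0.40, without _x_at and _s_at probe sets; BNIP3, CCND1, MPO and TIPARP, all near 0, also changed sign under some alternative. In all, where the gene was still measured, CYBA's change of sign and 28 other alternatives took a named gene below 2-fold, and 12 took one above it. Signals near the floor limit the folds of dim genes: with the floor at the 75th percentile, 11 named genes that were still measured were below 2-fold. FICD, SEC24D, PPP1R15A, SELENOP and TINCR had log2 ratios of 0.86, 0.82, 0.28, 0.13 and 0.16, and ITGA8, PAQR4, IGFBP2, GJB2, UNC13C and GDAP1 of -0.95, -0.73, -0.55, -0.41, -0.28 and -0.16. Further named genes past 2-fold lay below this floor of 170.5 in both samples. They lost their call without entering this count, and include NOG, ILDR2, GINS2, GBP2, PAX5, SPARC, BLNK, NFE2, MT1G and BHLHE41.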

Other observations

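The lists in this part were chosen after the data were seen. Some histone genes were higher in the eltrombopag sample. Of 45 genes examined from the H1, H2A, H2B, H3 and H4 histone families, 30 lay below the floor in both samples. Of the 15 measured, 4 were at least 2-fold higher: H2BC21 at 5.96-fold, H2AC6 at 3.90-fold, H2BC12 at 2.92-fold and H2BC5 at 3.12-fold. For H2BC5 this held in 1 probe set, and another of like signal had a log2 ratio of 0.11. H4C11 was the 1 gene at least 2-fold lower, with a log2 ratio of -1.05. This call ended at -0.94, -0.91 and -0.93 after median centring, quantile normalization and lowess. As a list the histone genes did not stand apart, at percentile 94.0, and 94.6, 95.8 and 97.0 after median centring, quantile normalization and lowess. Similar sequences within the family mean that these are not independent measurements.

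Immediate early genes, which cells switch on soon after a stimulus, went both ways: of 18 measured, 10 had a ratio above 0 and 8 below, and 2 passed 2-fold. FOSB and FOS were 6.60-fold and 3.75-fold higher, EGR1 had a log2 ratio of 0.76 and JUNB 0.51, while JUN, IER2 and ATF3 had 0.03, -0.03 and -0.03, and FOSL2, KLF2 and ZFP36 had -0.51, -0.46 and -0.37. The list, with 19 measured genes after median centring and quantile normalization, lay at percentile 95.8 on the deposited scale and 95.5 after median centring, and at 97.7 and 98.7 after quantile normalization and lowess, so its place depended on the scaling. The promyelocyte and myeloid identity list lay at percentile 19.5, with CEBPA, a transcription factor of granulocyte precursors, 2.93-fold lower and FUT4, which makes the CD15 antigen, at 0.57.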
